A study of Tupaia belangeri chinensis with 36 samples.

How the data were processed

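The series measured messenger RNA by poly(A) RNA-seq with paired reads of 150 nt and small RNA by single reads of 50 nt in the testis, the caput (head) and the cauda (tail) of the epididymis of the Chinese tree shrew. Animals were males of 1.5 to 2 years, collected in a non-reproductive season (NR, December 2023) and a reproductive season (R, April 2024). Each of the 6 groups of tissue and season had 3 biological replicates in each assay, 36 samples in all, and RNA integrity numbers were at least 7, per the labels. Season and collection date could not be told apart, because each season was collected at 1 time.

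The authors deposited 4 tables of raw counts, with 1 column per sample and no normalization: 27777 genes, 1210 miRNAs, 59590 piRNAs and 146 piRNA clusters. The submitters' processing notes name featureCounts and bedtools, and the versions, the aligner and the genome build are not given in the sources used here. The deposited cluster values are expected counts, with fractions, and they were rounded to whole numbers before testing. The design text of the series says that the authors compared seasons within each tissue with DESeq2. Gene identifiers were those of a tree shrew database, and 0 of the 27777 matched the reference table of gene symbols, so genes are given by identifier, at most 2 in each direction under the rule below, and the 42 gene lists planned for this tissue could not be tested. Of the miRNA names, 491 carried a mouse prefix and 719 carried a prefix that marks new entries, and the latter are reported without their names. piRNA sequences and cluster coordinates were not analysed here.

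Some deposited columns were not separate measurements. Among miRNA columns 2 (TESTIS-NR 2 and CAPUT-NR 2), among piRNA columns 2 (TESTIS-NR 3 and CAPUT-NR 3) and among cluster columns 4 (TESTIS-NR 3, CAPUT-NR 3, CAUDA-NR 3 and CAPUT-R 3) equalled the mean of the other 2 columns of their group at 100% of features. The comparison let a rounded mean end in the next whole number up and allowed the clusters a relative difference of 1e-06. In the measured columns the highest share of such features was 2.04% for genes, 4.93% for miRNAs, 41.9% for piRNAs, where most values were low, and 0.685% for clusters. The averaged columns were left out of all tests, a choice made after the tables were examined, so n was 2 in the groups concerned. The RNA-seq table had 0 averaged columns. For TESTIS-NR and CAPUT-NR the averaged column was number 2 in miRNAs and number 3 in piRNAs and clusters. That a number stands for the same small RNA library in each of these was taken from the column names and not tested.

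Total counts of the measured libraries ran from 26703225 to 37174187 for genes, from 2166152 to 14756858 for miRNAs, from 9367 to 6440714 for piRNAs and from 11811.5 to 7367670 for clusters. The 10 most abundant features took 67.1% to 75.1% of the counts of a miRNA library. Molecular identifiers are not given in the sources used here, so floors of 3 counts, taken over a group, cover counting error only.

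Seasons were compared as R minus NR within each tissue with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, default filter on low counts), and features with a Benjamini-Hochberg adjusted p under 0.05 were called. Caput and cauda were compared with season as a covariate, and the difference of the season changes (caput minus cauda) was tested as an interaction. Of 17 miRNA lists fixed before the data were examined, those with at least 3 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01: 14 in the testis, 15 in the caput and 15 in the cauda. The miR-506 to 514 family and the miR-888 cluster had fewer than 3 measured members in every tissue and were not tested. Levels are CPM, counts relative to the library size after TMM scaling, as mean ± SD, and changes are log2 with standard errors (SE). Totals of piRNA counts were compared with two-sided exact permutation tests of the difference of mean log2 totals.

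The designs, the lists, the alternatives and the naming rule were fixed before the data were examined. The rule took, per comparison, the called features with non-overlapping groups, a mean in the higher group of at least 10 CPM (5 CPM for genes and between segments) and, of these, the largest changes. In the interaction it took the called features with the smallest p in each direction. For miRNAs it also took the 5 highest means of each tissue and up to 4 list members with the smallest p. Alternatives were scaling by library total or DESeq2 size factors, no filter, a log2 fold of at least 1, DESeq2 1.42.0, a replicate block, all libraries of an assay in 1 fit, an estimated correlation for lists, and leaving out each library. Chosen after the data were examined were the averaged columns kept, piRNA libraries scaled to miRNA totals, a wider match of miRNA names, and NR libraries numbered 3 left out of both segments.

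Replicate numbers were checked for pairing through deviations from group means, which correlated in RNA-seq between caput and cauda libraries of the same number in all 6 pairs (0.188 to 0.229 in NR, 0.160 to 0.283 in R), and were negative for every other pairing of numbers within a season. Deviations from a group mean sum to 0, so the negative values follow in part from the same-number ones and are no separate evidence. The numbers were taken, as an assumption, to pair caput with cauda RNA-seq libraries, by the data and not by a label. Caput RNA-seq libraries of the same number in different seasons, which the collection dates keep from being 1 animal, gave 0.0302, 0.282 and 0.371, so such values also arise without a shared animal. Same-number values reached 0.275 between caput and testis in RNA-seq and 0.295 in miRNAs. In R, same-number RNA-seq values were 0.0488 to 0.0697 between caput and testis and 0.0521 to 0.0871 between cauda and testis. Every other pairing of numbers was negative there, but these values lay under the pairing threshold of 0.1. In NR the same-number values ran from -0.0315 to 0.275 between caput and testis and from -0.0927 to 0.00994 between cauda and testis. The replicates of TESTIS-NR were also examined by rank correlation, by principal components and by a position between the seasons, all chosen after the data were examined. A position places a library between the other NR (0) and R (1) libraries, over genes of at least 1 CPM. It is a ratio of mean cross-products of differences between libraries, in which no library enters both factors of a product. The divisor is the same mean for the R libraries. Where NR libraries differ among themselves as much as the seasons do, this divisor can be near 0 or negative, and a position is then not a distance.

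On simulated counts with known changes the RNA-seq season test recovered 0 of 100 genes changed 4-fold and 48 of 100 changed 16-fold in the testis, 42 and 84 in the caput, and 59 and 87 in the cauda. For miRNAs it recovered 16 of 30 changed 16-fold in the testis, 9 in the caput and 27 in the cauda. For piRNAs it recovered 29 of 100 changed 16-fold in the testis and 0 in the caput and cauda. Unchanged features made up 1 of 49 calls in testis genes, 11 of 137 in the caput and 13 of 159 in the cauda. For miRNAs they made up 4 of 23, 0 of 10 and 3 of 48 calls, and for testis piRNAs 8 of 39. Simulated caput and cauda piRNAs gave 0 calls over 148 and 434 features, where the measured ones gave 7 of 220 and 76 of 890. Those simulations were thus unlike the measured counts.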

Results

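Testis, caput and cauda epididymis of male tree shrews, small mammals related to primates, were profiled in a non-reproductive (NR) and a reproductive (R) season. The epididymis stores and matures sperm, and its caput receives sperm from the testis before they pass to the cauda. There were 18 RNA-seq and 18 small RNA libraries, 3 per tissue and season. RNA-seq totals were 26703225 to 37174187 counts per library and miRNA totals 2166152 to 14756858. In the small RNA tables the averaged columns were left out, which leaves n = 2 in some groups. In RNA-seq the first principal component held 70.4% of the variance and separated testis from epididymis, and the second held 8.50% and separated caput from cauda.

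**Figure D1:**
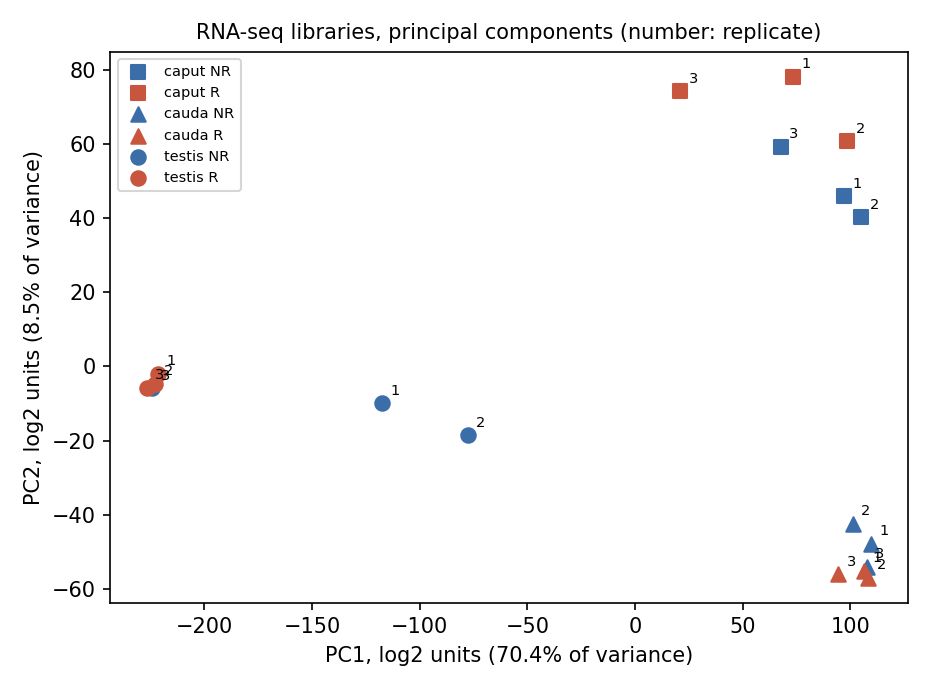
RNA-seq libraries on the first and second principal components, in log2 units, with symbols for tissue, colours for season and numbers for replicates. TESTIS-NR 3 overlaps the 3 TESTIS-R libraries, while TESTIS-NR 1 and 2 lie between these and the epididymis, and the first component holds 70.4% of the variance.

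The first question was how the testis transcriptome differs between seasons. The 3 TESTIS-NR libraries were not alike: TESTIS-NR 3 had rank correlations of 0.969 to 0.974 with the TESTIS-R libraries, and of 0.902 and 0.839 with TESTIS-NR 1 and 2. Between the seasons TESTIS-NR 3 took position 0.982, where the TESTIS-R libraries took 0.941 to 1.06. TESTIS-NR 1 and 2 took -29.8 and -25.7. Every library but TESTIS-NR 3 was set against NR libraries that included it, so these positions are not on the same scale. The values of TESTIS-NR 1 and 2 are ratios and not distances between the seasons. With all 6 libraries 0 of 17788 genes were called by edgeR's quasi-likelihood test, and 3021 had an unadjusted p under 0.05, 246 higher and 2775 lower in R, where DESeq2 called 69 higher and 566 lower. Without TESTIS-NR 3, edgeR called 9955 genes, 4614 higher and 5341 lower in R. Fitting all 18 RNA-seq libraries together gave 167 higher and 2385 lower. Scaling by library total moved the median log2 change of all testis genes from -0.04 to -0.36. Transcripts of 657 testis-enriched genes (mean of at least 20 CPM over the testis libraries and median under 1 CPM over the epididymal ones, a set chosen after the data were examined) took 3.44% and 2.52% of the counts in TESTIS-NR 1 and 2, 7.61% in TESTIS-NR 3 and 7.40% to 7.48% in TESTIS-R. The mean over these same libraries favours genes high in most of them, so part of the difference is built in.

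Testis miRNAs of the miR-34 and miR-449 families, which are abundant in meiotic and postmeiotic germ cells and in ciliated cells, were higher in R as a list. All 6 measured members had a positive change with a median log2 of 1.27, and camera gave an adjusted p of 0.0110 (adjusted p = 0.880 with an estimated correlation). That estimated correlation was 0.693, against the preset 0.01. The 6 include both arms of miR-34b and of miR-34c, so they are not separate members that agree. mmu-miR-34c-5p had 172 CPM in TESTIS-NR 1 and 2914 in TESTIS-NR 3, against 2968 to 4235 in the 3 TESTIS-R libraries. mmu-miR-449a-5p had 70.3 CPM in TESTIS-NR 1, 1027 in TESTIS-NR 3 and 1849 to 2477 in TESTIS-R. mmu-miR-34b-5p had 85.6 CPM in TESTIS-NR 1, 941 in TESTIS-NR 3 and 801 to 1658 in TESTIS-R. None of the 6 passed on its own, over all miRNAs or adjusted over the list alone. The list call was lost without TESTIS-NR 1 (adjusted p 0.237), TESTIS-R 1 (0.0554), TESTIS-R 2 (0.0554) or TESTIS-R 3 (0.0846), and alternatives gave adjusted p of 0.000124 to 0.880.

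**Figure D2:**
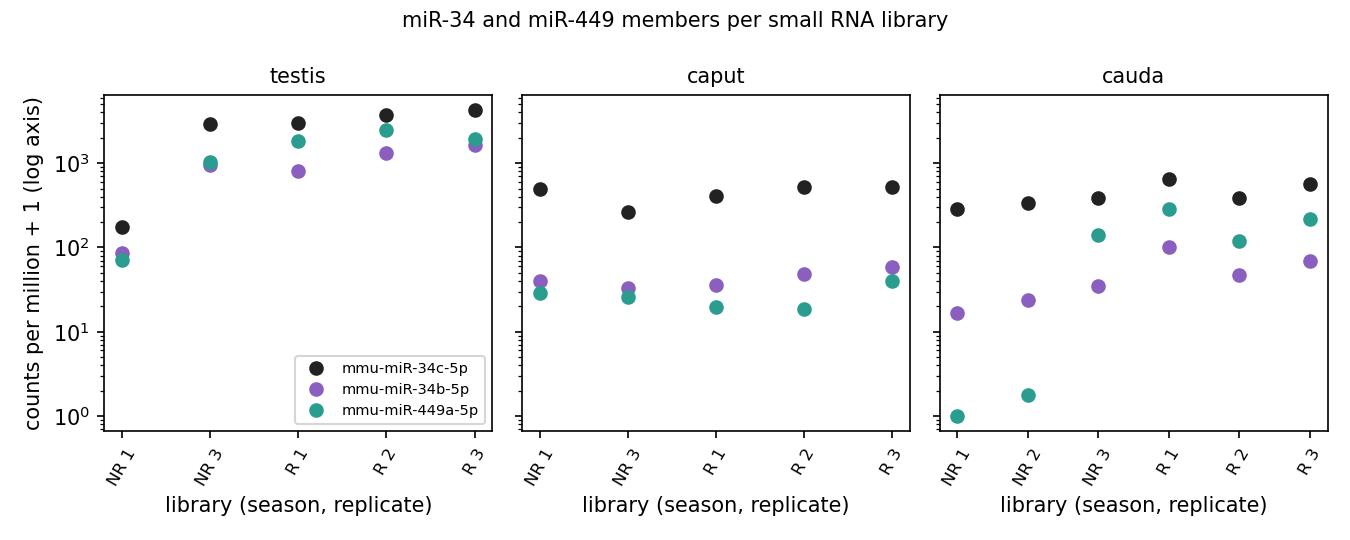
CPM + 1 on a log axis of mmu-miR-34c-5p, mmu-miR-34b-5p and mmu-miR-449a-5p in each measured small RNA library. In the testis mmu-miR-34c-5p lay at 172 CPM in NR 1 and at 2914 in NR 3, near the 2968 to 4235 of the R libraries.

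The muscle miRNAs (miR-1, miR-133, miR-143, miR-145 and miR-206, abundant in muscle cells) were lower in R testes as a list (camera adjusted p 0.0436, and adjusted p = 0.880 with an estimated correlation), although 3 of the 8 members, of miR-143 and miR-145, had a positive change. mmu-miR-206-3p had 69.1 CPM in TESTIS-NR 1, 418 in TESTIS-NR 3 and 29.1 to 35.4 in TESTIS-R. mmu-miR-1a-3p had 77.7, 583 and 54.5 to 63.8 CPM in the same order. The list of miR-10, miR-99, miR-100 and miR-125 was also lower in R, with 2 of 14 members positive (adjusted p 0.0436, and adjusted p = 0.880 with an estimated correlation), including mmu-miR-100-5p at 5504 ± 20.1 CPM (SD, n = 2) in NR and 3054 ± 439 (SD, n = 3) in R. Of the leukocyte miRNAs 1 of 8, mmu-miR-21a-5p, was lower adjusted over the list alone (60944 ± 5481 CPM in NR, n = 2, and 38079 ± 2655 in R, n = 3), and 0 passed over all miRNAs. The other 10 lists tested in the testis (miR-200, let-7, erythrocyte, miR-17 to 92, imprinted DLK1-DIO3, miR-29, miR-30, miR-181, testis-enriched, and epithelial and stem cell miRNAs) gave adjusted p of 0.0828 to 0.894, and the leukocyte list 0.256. Among lists that were not called, the median, the mean and the test differed in sign for the erythrocyte, DLK1-DIO3 and miR-181 lists in the testis, for the DLK1-DIO3, miR-181, miR-183 and testis-enriched lists in the caput, and for the miR-17 to 92 list in the cauda. Over all 496 miRNAs tested edgeR called 0, with 36 at an unadjusted p under 0.05, and DESeq2 called 27. Without TESTIS-NR 1 the list calls numbered 2, without TESTIS-NR 3 6, without TESTIS-R 1 there was 1, and without TESTIS-R 2 or 3 there were 0. The muscle call was lost without any 1 of the TESTIS-R libraries (adjusted p 0.0554 to 0.141), and the call of miR-10, miR-99, miR-100 and miR-125 without TESTIS-NR 1 (0.293), TESTIS-R 2 (0.0735) or TESTIS-R 3 (0.116) and with the replicate block (0.0843).

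The most abundant testis miRNAs were mmu-miR-101a-3p at 211336 ± 36841 CPM (SD, n = 2) in NR and 193127 ± 3535 (SD, n = 3) in R, and mmu-miR-101c, with nearly the same values. Their sequences are near-identical and reads can count for both, so both levels are uncertain. mmu-miR-29c-3p had 67281 ± 14635 CPM in NR (n = 2) and 66082 ± 4151 in R (n = 3), and mmu-miR-125b-5p 41601 ± 18123 and 51273 ± 865. None of these passed.

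piRNAs, small RNAs that guide PIWI proteins against transposons in germ cells, had higher total counts in R testes. Their total was 5040407 ± 1227282 counts in R (SD, n = 3) and 204199 ± 78763 in NR (SD, n = 2), 24.7-fold higher in R, with every R library above both NR libraries. A two-sided exact permutation test gave p = 0.1, the smallest p possible with these n, and 0.3 after adjustment. The TESTIS-NR column numbered 3, the number of the RNA-seq library that lay with R, is averaged in this table and so was not measured. The labels do not say that the RNA-seq and small RNA libraries of that number come from 1 animal. In RNA-seq the libraries numbered TESTIS-NR 1 and 2 also had lower shares of testis-enriched transcripts (3.44% and 2.52%) than TESTIS-R (7.40% to 7.48%). That gene set was chosen on the mean of the same testis libraries, so this difference is in part built in. A change in the cell content of the testis was not separated from a change within cells. Counts of piRNA clusters, genome regions that give rise to piRNAs, were 23.9-fold higher in R testes (exact permutation p = 0.1).

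**Figure D3:**
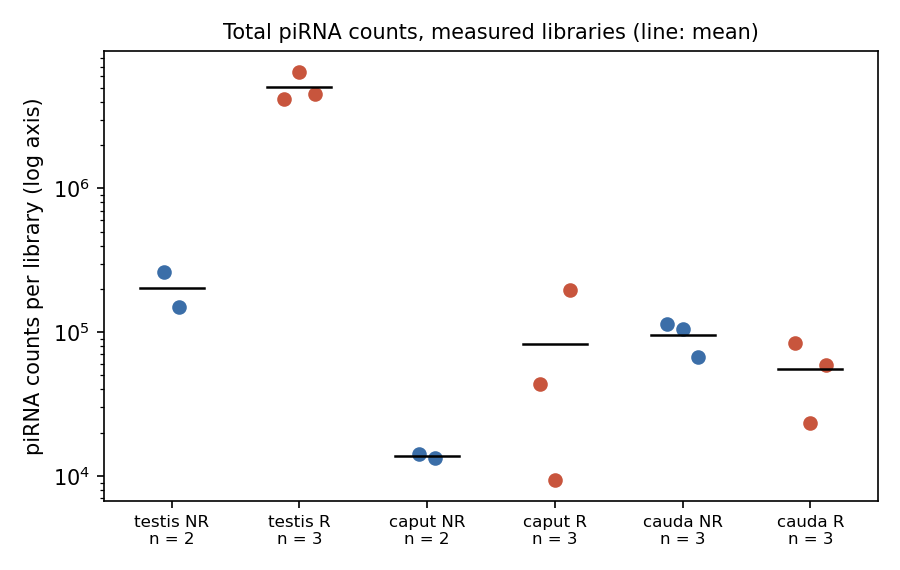
Total piRNA counts per measured library on a log axis, by tissue and season, with a line at each mean. The 3 TESTIS-R libraries average 5040407 counts against 204199 in the 2 measured TESTIS-NR libraries.

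Relative to the other piRNAs of the testis, 160 of 40091 were higher and 208 lower in R. pir-tup-24716 had 0 counts in both TESTIS-NR libraries and 413 ± 102 CPM in TESTIS-R (SD, n = 3), at least 78.7-fold higher over the floor of 3 counts (edgeR adjusted p 2.69e-06). pir-tup-21768 was at least 75.6-fold higher, with 397 ± 98.9 CPM in R. pir-tup-51371 was at least 11426-fold lower, from 3021 ± 80.9 CPM in NR (SD, n = 2) to 0 counts in R (adjusted p 5.23e-12). At the same scaling these bounds were 32.4 and 31.1 without TESTIS-NR 1, 46.3 and 44.5 without TESTIS-NR 2, and 6716 for pir-tup-51371 without TESTIS-R 2. pir-tup-5146 had 7133 ± 6160 CPM in NR (11489 in TESTIS-NR 1 and 2777 in TESTIS-NR 2) and 0.653 ± 0.286 in R. The split depended on scaling: library totals gave 45 higher and 320 lower, DESeq2 size factors 70 and 236, and scaling to miRNA totals 40522 and 45. The replicate block gave 173 higher and 111 lower, and all measured piRNA libraries in 1 fit 21 and 265. DESeq2 called 672 and a fit with no filter 222. Without TESTIS-NR 1 there were 706 higher and 235 lower, without TESTIS-NR 2 45 and 86, without TESTIS-R 1 18 and 115, without TESTIS-R 2 71 and 262, and without TESTIS-R 3 13 and 85.

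Among testis piRNA clusters 3 were higher and 29 lower in R within the table. clu_146 had 1472 ± 601 CPM in NR (SD, n = 2) and 4844 ± 2016 in R (SD, n = 3), and clu_25 had 1282 ± 641 and 3527 ± 559. clu_29 had 439 ± 374 CPM in NR and 2.94 ± 0.288 in R, and clu_5 had 401 ± 352 and 2.74 ± 0.0773, where TESTIS-NR 1 had 174 and 152 CPM and TESTIS-NR 2 703 and 650. Scaling to miRNA totals gave 137 higher and 6 lower, DESeq2 called 55, all 14 measured cluster libraries in 1 fit gave 13, and the replicate block 21. Without TESTIS-NR 1 there were 88 calls, without TESTIS-R 1 14 and without TESTIS-R 3 11.

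In the caput no gene and no miRNA was called between seasons. edgeR called 0 of 17059 genes, with 1179 higher and 1499 lower in R at an unadjusted p under 0.05, and DESeq2 called 487 higher and 387 lower. The CAPUT-R 3 library carried transcripts of the 657 testis-enriched genes at 0.625% of its counts, where CAPUT-NR 3 had 0.221% and the other caput libraries 0.0189% to 0.108%. Fitting all 18 RNA-seq libraries gave 4 genes, and leaving out CAPUT-NR 1 gave 1. Of 534 miRNAs edgeR called 0, with 24 at an unadjusted p under 0.05, and DESeq2 called 20. The leukocyte miRNAs had a negative change in all 9 members with a median log2 of -0.37, and the miR-17 to 92 list a median of -0.38 with 4 of 17 members positive, both with an adjusted p of 0.0882. The other 13 caput lists, miR-34 and miR-449 included, gave adjusted p of 0.531 to 0.803. mmu-miR-34c-5p had 382 ± 165 CPM in NR (SD, n = 2) and 478 ± 66.4 in R (SD, n = 3). Without CAPUT-R 2 there were 2 list calls.

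The caput held few piRNA counts, with a mean of 82759 in R and 13846 in NR, 5.98-fold higher (exact permutation p = 0.4), and CAPUT-R 3 alone had 195386. The RNA-seq library of that number had the highest caput share of testis-enriched transcripts. Without CAPUT-R 3 the ratio was 1.91. edgeR called 7 of 220 piRNAs, all lower in R, at 13360 and 14332 counts per NR library. pir-tup-41772 had 6235 ± 2540 CPM in NR (SD, n = 2) and 0 counts in R, at least 179-fold lower (adjusted p 0.0296), and pir-tup-5584 had 3470 ± 672 CPM in NR and 0 counts in R, at least 99.7-fold lower. These bounds were 114 and 63.5 without CAPUT-R 1, and 76.8 and 42.7 without CAPUT-R 3. Library totals gave 1 call, while DESeq2, no filter, the replicate block and miRNA totals gave 0 each. All measured piRNA libraries in 1 fit gave 99 calls, and leaving out CAPUT-NR 1, CAPUT-NR 2, CAPUT-R 1, CAPUT-R 2 and CAPUT-R 3 gave 21, 22, 4, 160 and 0, with 27 of the 160 higher in R. Of 98 caput clusters edgeR called 0, with 17 at an unadjusted p under 0.05 and n = 2 per season, DESeq2 called 33, and all measured cluster libraries in 1 fit gave 24.

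In the cauda 2 of 16454 genes were called between seasons, both lower in R. TSDBGID.22142 fell by 3.62 on the log2 scale (SE 0.20, edgeR adjusted p 0.0116), from 41.5 ± 8.14 CPM in NR to 3.37 ± 0.161 in R (SD, n = 3 each). TSDBGID.2254 had 20.5 ± 5.62 CPM in NR and 0.0111 ± 0.0192 in R (SD, n = 3 each, adjusted p 0.0160). At an unadjusted p under 0.05 there were 2062 higher and 2146 lower genes, and DESeq2 called 1177 and 1055. The replicate block gave 0 calls. Neither gene was among the 2 calls with all 18 RNA-seq libraries in 1 fit or the 2 without CAUDA-R 2, and TSDBGID.2254 was lost without CAUDA-NR 1 or CAUDA-NR 2. Without CAUDA-NR 1 there were 4 calls, without CAUDA-NR 3 901, 448 of them higher in R, and without CAUDA-R 1 or CAUDA-R 3 there were 0.

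Cauda miRNAs of the miR-183, miR-96 and miR-182 cluster, which are made from a common precursor and abundant in sensory and other epithelia, were higher in R as a list, with all 3 members positive (camera adjusted p 0.0449, and adjusted p = 0.829 with an estimated correlation). mmu-miR-183-5p had 336 ± 64.9 CPM in NR and 1008 ± 342 in R (SD, n = 3 each, log2 change 1.59, SE 0.30, edgeR adjusted p 0.0502). mmu-miR-182-5p had 5172 ± 933 CPM in NR and 15026 ± 5406 in R (log2 change 1.54, SE 0.30, adjusted p 0.0551). Both passed when adjusted over the list alone, and neither over all miRNAs. mmu-miR-96-5p had 78.5 ± 26.8 and 140.8 ± 42.6 CPM. The list call was lost with DESeq2 size factors (adjusted p 0.0520) and when any 1 library was left out, and alternatives gave adjusted p of 0.0284 to 0.829. The number of list calls was 2 without CAUDA-NR 3 and 0 without each of the other 5 libraries.

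Leukocyte miRNAs had lower cauda levels in R in 8 of 10 members, with a list adjusted p of 0.128, and 2 were lower adjusted over the list alone. mmu-miR-146a-5p, an immune regulator, had 84.3 ± 29.6 CPM in NR and 30.4 ± 6.37 in R (SD, n = 3 each), and mmu-miR-150-5p, a lymphocyte miRNA, 20.6 ± 4.01 and 10.3 ± 0.989. mmu-miR-34b-5p had 24.3 ± 9.31 CPM in NR and 71.0 ± 26.9 in R, and the miR-34 and miR-449 list gave an adjusted p of 0.140. That list was called without CAUDA-NR 3 (adjusted p 0.0386), and alternatives gave 0.0386 to 0.829. mmu-miR-449a-5p had 0 and 0.785 CPM in CAUDA-NR 1 and 2, 140.4 in CAUDA-NR 3 and 116.7 to 287.9 in CAUDA-R. The other 12 lists gave adjusted p of 0.260 to 0.962.

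Over all 455 cauda miRNAs 10 were called higher and 4 lower in R, all without a mouse name. The submitters' prefix marks all 14 as new entries, and whether they are true miRNAs was not tested. Only 3 of the higher and 1 of the lower reached a mean of 10 CPM, which the naming rule asks for. Of these, 1 had 0 counts in CAUDA-NR and 43.0 ± 9.81 CPM in CAUDA-R (SD, n = 3), at least 366-fold higher (edgeR adjusted p 0.0171). Another was at least 212-fold higher, with 24.9 ± 14.6 CPM in R, and 1 more had 2.41 ± 0.622 CPM in NR and 10.3 ± 2.41 in R (adjusted p 0.0493), the smallest change of the 10. The other 7 had 0 counts in NR and means of 1.97 to 7.48 CPM in R. Of the 4 lower ones, 1 had 10.2 ± 5.50 CPM in NR and 0 counts in R, at least 83.4-fold lower. The other lower ones also had 0 counts in R, with means of 3.39 to 9.60 CPM in NR. Without CAUDA-NR 2 the bounds of the higher ones were 202 and 117, without CAUDA-R 3 the latter was 141, and without CAUDA-R 1 that of the lower one was 48.8. DESeq2 called 48, no filter 1, and the replicate block and all measured miRNA libraries in 1 fit 0 each. Without CAUDA-NR 1, CAUDA-NR 2 or CAUDA-R 3 there were 0 calls, without CAUDA-NR 3 24, without CAUDA-R 1 4 and without CAUDA-R 2 1, of which 7, 1 and 0 were among the 14.

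The cauda piRNA total was 55406 ± 30313 counts in R and 95546 ± 24817 in NR (SD, n = 3 each, exact permutation p = 0.2), 1.72-fold higher in NR. Cluster counts went the other way, with 88489 ± 51487 in R (SD, n = 3) and 37131 ± 4119 in NR (SD, n = 2), 2.38-fold higher in R (exact permutation p = 0.3). The piRNA total rests in part on few entries. pir-tup-27559 held 17.9%, 21.4% and 14.8% of the piRNA counts of CAUDA-NR 1, 2 and 3, and at most 0.221% in CAUDA-R. pir-tup-9537 held 19.6%, 18.4% and 2.51%, and at most 0.145% in CAUDA-R. The 10 most abundant entries took 5.74% to 69.3% of a cauda library. edgeR called 76 of 890 piRNAs, all lower in R. pir-tup-9465 had 28311 ± 37337 CPM in NR (SD, n = 3) and 0 counts in R, at least 1500.0-fold lower, and pir-tup-9579 had 17016 ± 17926 CPM and was at least 902-fold lower. Both means rest on CAUDA-NR 2, with 71229 and 36083 CPM, and the bounds were 363 and 396 without it, 763 and 458 without CAUDA-R 1, and 957 and 575 without CAUDA-R 3. Library totals gave 32 calls, no filter 0, DESeq2 221 with 66 higher, miRNA totals 45, the replicate block 42 and all measured piRNA libraries in 1 fit 268. Without CAUDA-NR 1, 2 and 3 there were 115, 15 and 1047 calls, and without CAUDA-R 1, 2 and 3 there were 0, 42 and 0. Without CAUDA-NR 3 the direction turned, with 846 higher and 201 lower in R, and without CAUDA-R 2 there were 14 higher and 28 lower.

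Of 119 cauda piRNA clusters 55 were higher and 56 lower in R than in CAUDA-NR 1 and 2. CAUDA-NR 3, which took position 0.844 between the seasons in piRNAs, is an averaged column in this table and so was not measured. clu_53 had 349736 ± 101602 CPM in NR (SD, n = 2) and 2110 ± 596 in R (SD, n = 3, edgeR adjusted p 5.82e-06), and clu_122 had 28576 ± 14543 and 134 ± 83.1. clu_146 had 69.2 ± 1.84 CPM in NR and 3604 ± 1984 in R, and clu_1 had 0 counts in NR and 637 ± 233 CPM in R, at least 15.3-fold higher (9.03 without CAUDA-NR 1 and 6.25 without CAUDA-NR 2). Scaling to miRNA totals gave 69 higher and 35 lower, and the replicate block 23 and 41. Without CAUDA-NR 2 there were 67 higher and 16 lower, and without CAUDA-NR 1 65 and 45.

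Caput and cauda were then compared with season as a covariate. Among the named miRNAs were muscle miRNAs, which were not tested as a list between segments: mmu-miR-206-3p was 12-fold higher in cauda (144 ± 59.2 CPM in caput, n = 5, and 1817 ± 744 in cauda, n = 6, edgeR adjusted p 0.000253), mmu-miR-1a-3p 9.0-fold, mmu-miR-133b-3p 8.17-fold and mmu-miR-133a-3p 6.92-fold. mmu-miR-196b-5p, whose gene lies in a Hox cluster, was 8.69-fold higher in cauda (225 ± 61.8 and 2010.5 ± 444 CPM, adjusted p 2.22e-06), and mmu-miR-196a-2-3p 11.1-fold. mmu-miR-376a-3p, of the imprinted DLK1-DIO3 region, was 6.63-fold higher in cauda.

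Higher in caput were members of the miR-135 family, with mmu-miR-135a-5p at 18428 ± 7062 CPM in caput (SD, n = 5) and 366 ± 135 in cauda (SD, n = 6), 50.4-fold (edgeR adjusted p 6.76e-06), and mmu-miR-135b-5p 9.30-fold. mmu-miR-192-5p and mmu-miR-194-5p, which are made from common precursors and abundant in intestinal and renal epithelium, were 26.8-fold and 14.2-fold higher in caput. A new entry without a mouse name was among the 5 most abundant of the caput, with 90205 ± 51095 CPM against 5775 ± 3388 in cauda, 15.8-fold higher. In total 79 of 620 miRNAs were higher and 53 lower in caput. Scaling by library total gave 41 higher and 84 lower and moved the median log2 difference from 0.05 to -0.34, with no reversal of a named miRNA. The replicate block gave 76 calls, and leaving out both NR libraries numbered 3 gave 87.

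**Figure D4:**
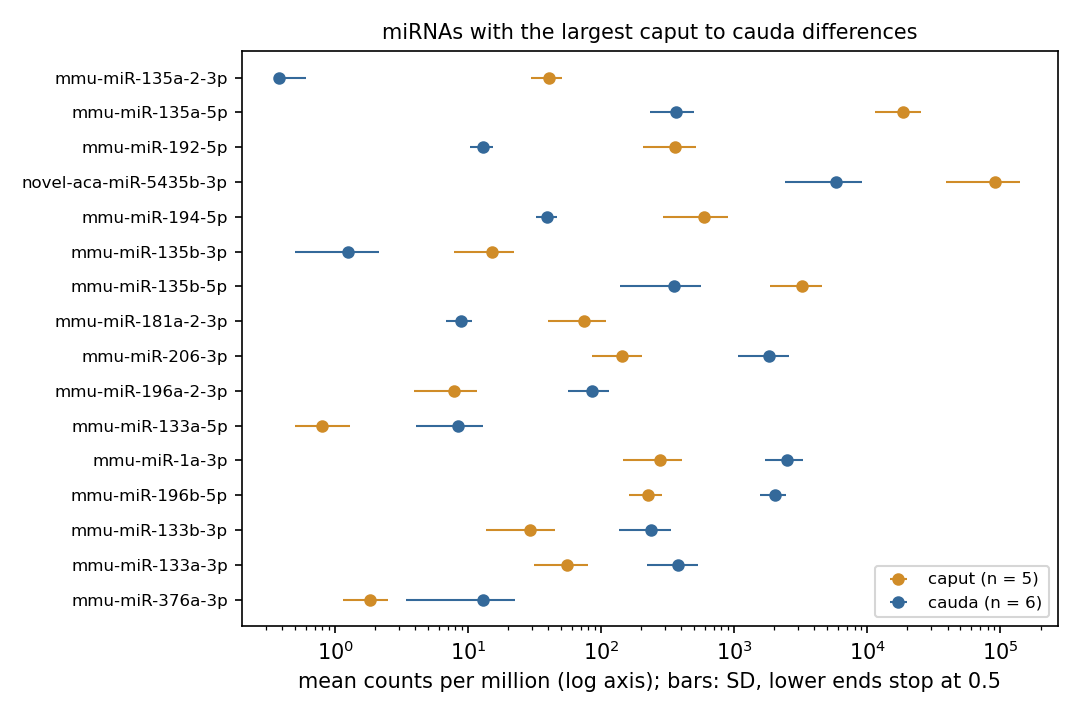
Mean CPM on a log axis of the named miRNAs in caput (n = 5) and cauda (n = 6), with SD bars. mmu-miR-135a-5p is 50.4-fold higher in caput and mmu-miR-206-3p is 12-fold higher in cauda.

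In RNA-seq 2499 of 17947 genes were higher and 2207 lower in caput than in cauda, and 2488 differed at least 2-fold. TSDBGID.21271 had 181 ± 78.8 CPM in caput (SD, n = 6) and 0 counts in all 6 cauda libraries, at least 10577-fold higher (edgeR adjusted p 5.67e-05), and TSDBGID.9794 was at least 1811-fold higher. TSDBGID.5213 was 88.2-fold higher in cauda, with 1.56 ± 0.800 CPM in caput and 142 ± 91.1 in cauda, and TSDBGID.5214 was 39.1-fold higher.

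The season changes of caput and cauda differed for 5 of 17947 genes, 4 with a higher and 1 with a lower change (R minus NR) in caput. TSDBGID.21639 went from 28.7 ± 6.24 CPM in NR to 58.6 ± 4.59 in R in caput, and from 31.8 ± 9.66 to 9.03 ± 0.897 in cauda (SD, n = 3 each), a log2 difference of 2.84 (SE 0.34, edgeR adjusted p 0.0458). TSDBGID.24059 went from 29 ± 16.9 to 1.47 ± 0.0708 CPM in caput and from 1.44 ± 0.474 to 1.84 ± 0.277 in cauda, a difference of -4.64 (SE 0.59, adjusted p 0.0458). With the replicate block, which pairs the segments, the count was 0, as with library totals, while no filter gave 2 and DESeq2 232. Without CAPUT-NR 1, CAUDA-NR 1, CAPUT-R 1, CAPUT-R 3, CAUDA-R 1 or CAUDA-R 2 there were 0, without CAUDA-R 3 1, without CAUDA-NR 2 2, without CAPUT-NR 2 3 and without CAUDA-NR 3 20, of which 0, 0, 2 and 5 were among the 5. For miRNAs edgeR called 0 of 620, with 35 at an unadjusted p under 0.05, and DESeq2 called 13; without CAPUT-NR 3 or CAPUT-R 2 there was 1.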

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

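The tests on TESTIS-NR 3 and on library depth were chosen only after the result was seen, and keeping averaged columns was an alternative added after seeing the data, while the bounds for testis-enriched transcripts, for replaced libraries and for splits were written before their results.

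The season change differed between caput and cauda, by the interaction test, for 5 genes, named here after their values were seen. The log2 differences (caput minus cauda) were 2.84 for TSDBGID.21639, 9.89 for TSDBGID.23420, 2.55 for TSDBGID.13325, 4.15 for TSDBGID.3762 and -4.64 for TSDBGID.24059, each with an edgeR adjusted p of 0.0458. TSDBGID.23420 averaged 0.0478 CPM in CAPUT-NR, 12.6 in CAPUT-R, 10.1 in CAUDA-NR and 2.54 in CAUDA-R, so its log2 difference rests on a group near 0. TSDBGID.13325 averaged 80.7, 370.1, 29.8 and 23.4 CPM in the same order, and TSDBGID.3762 averaged 2.02, 16.5, 1.38 and 0.633. Of 40 splits drawn, the real one included, 1 gave as many genes (5 in the real split and at most 2 in the others). Only 2 of the 39 other splits kept all 6 caput and cauda pairs together as the real one did, with 0 calls each, while the others parted up to 6 pairs, so like splits are too few to exclude chance. With the replicate block, which keeps the pairs, the count was 0.

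TESTIS-NR 3 lay with the reproductive testes in RNA-seq. A swap with a TESTIS-R library would need a TESTIS-R library placed among the NR testes, and the lowest position of a TESTIS-R library was 0.940647, which argues against a swap. A wrong label on the RNA-seq library alone stays open, as 4 of the 6 miR-34 and miR-449 members of the small RNA library of that number were nearer to the R mean. An animal in another reproductive state than its group, or a label wrong for the whole animal, also stays open. The caput and cauda positions of NR 3 were 0.830 and 0.562294, between the seasons. Both passed the bound set for this cause after the result was seen. The test could only argue against this cause or leave it open, and the testis piRNA column of that number is averaged. These remaining explanations cannot be told apart, since the labels do not tie the testis libraries to the epididymis libraries.

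CAPUT-R 3 carried testis-enriched transcripts, of 657 genes with a mean of at least 20 CPM over the testis libraries and a median under 1 CPM over the epididymal ones. Depth as the source is argued against, as the library's total was 1.14933 times the mean of the other caput libraries while the set's share was 0.625% against at most 0.221%, in CAPUT-NR 3. RNA of testis or sperm in the sample stays open: 89.9543% of the set lay above the highest other caput library, just short of the bound of over 90% written beforehand. Over the 613 genes with at least 20 CPM in R testes, the median level was 8.50% of the R testis level, with quartiles of 7.31% and 9.52%. The set took 0.108% and 0.0296% of the counts in CAPUT-R 1 and 2, and 0.0360% to 0.0605% in CAUDA-R. The bound on the epididymal median leaves out transcripts common in those libraries, so low shares there are in part built in. Sperm within the reproductive caput is a biological source that was not separated from tissue carried over.

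Keeping averaged columns as libraries raised calls, from 0 to 9 in testis miRNAs, from 368 to 1203 in testis piRNAs and from 0 to 79 in caput clusters. Among testis lists it lowered them. The muscle list and the list of miR-10, miR-99, miR-100 and miR-125 lost their calls, each with a camera adjusted p of 0.0727. When each of the 6 cauda miRNA libraries was replaced in turn by the mean of the other 2, all 6 gave more calls than leaving that library out, such as 101 against 24 for CAUDA-NR 3 and 25 against 0 for CAUDA-NR 1. This is in line with an averaged column counting as a library without adding spread, and no biological explanation was tested.

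For season within a tissue, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real and highest other counts were 0 and 0 for testis genes (10 splits as large), 0 and 2 for caput genes (10), 2 and 1 for cauda genes (1), 14 and 1 for cauda miRNAs (1), 76 and 0 for cauda piRNAs (1), and 1 and 5 for cauda miRNA lists (4). For caput against cauda, 1 of 40 splits drawn for genes and 1 of 100 for miRNAs gave as many calls (4706 against at most 4, and 132 against at most 37). With libraries taken as unpaired, this is a share under 0.05. Of the 39 other splits of genes 5 parted all 6 pairs, as the real one did, with at most 0 calls, and the others parted fewer. Such like splits alone are too few for a share under 0.05. For the miRNA interaction, 100 of 100 splits gave at least the 0 of the real one, and the highest was 4.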

How the results depend on the processing

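Of 288 comparison values under alternatives 178 lay within 1.5 times the main count or its replicate spread and 110 did not. Of 1383 values of named features and lists 1248 kept their side of the threshold, 10 gained a call and the rest lost the call. With a call in either fit, 0 changed direction. Changes of direction between uncalled values were counted as kept. The cause of these changes was not tested. Averaged columns kept, miRNA totals and NR 3 left out of both segments were chosen after seeing the data. Where leaving out a library left 1 in a group, that sample is assumed to vary like the others. Planned gene lists, sequence weights, pseudocounts and quantile normalization were not run, for lack of gene names, sequences and normalized values.

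DESeq2 called 635 testis, 874 caput and 2232 cauda genes, 27, 20 and 48 miRNAs, 672, 0 and 221 piRNAs, 55 testis and 33 caput clusters, and 232 genes and 13 miRNAs in the interaction. All libraries of an assay in 1 fit gave 2552 testis and 4 caput genes, 1 testis and 0 cauda miRNAs, 99 caput and 268 cauda piRNAs, and 13 testis and 24 caput clusters. Library totals gave 1 caput and 32 cauda piRNAs and 0 interaction genes. No filter gave 1 cauda miRNA, 222, 0 and 0 piRNAs in testis, caput and cauda, and 2 interaction genes. Scaling moved the median log2 change from 0.92 to 0.06 (library totals) and 5.33 (miRNA totals) in testis piRNAs, from -0.08 to -0.29 and 4.61 in testis clusters, from 2.22 to 3.36 and 5.44 in caput piRNAs, from -0.41 to -1.32 and -0.19 in caput clusters, from 1.13 to 2.57 and 1.36 in cauda piRNAs, and from -0.29 to -0.20 and 2.20 in cauda clusters. A log2 fold of at least 1 gave 2488 genes between segments. DESeq2 size factors gave 0 cauda lists. An estimated correlation gave 0 testis and 0 cauda lists.

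The replicate block gave 0 cauda genes, 0 cauda miRNAs, 0 caput and 42 cauda piRNAs, 21 testis and 64 cauda clusters, 76 miRNAs between segments, 0 interaction genes and 1 caput list, and it moved no other count by over 1.5 times. Only caput and cauda RNA-seq numbers were taken as pairs, which is an assumption. Elsewhere libraries share only a number, with same-number correlations of -0.166 to 0.371.

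Averaged columns kept gave 9 testis and 3 caput miRNAs, 1203 testis and 78 caput piRNAs, 67 testis and 79 caput clusters, 1 interaction miRNA and 1 testis list. A wider match of miRNA names moved no count by over 1.5 times. Scaled to miRNA totals there were 40567 testis, 0 caput and 45 cauda piRNAs and 143 testis clusters, where the totals of TESTIS-NR 2 and CAPUT-NR 2 come from averaged miRNA columns. With NR 3 left out of both segments there were 87 miRNAs between segments, and 25 genes and 1 miRNA in the interaction.

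Leaving out each library gave 0 to 9955 testis, 0 to 1 caput and 0 to 901 cauda genes, 0 to 24 cauda miRNAs, 98 to 941 testis, 0 to 160 caput and 0 to 1047 cauda piRNAs, 11 to 88 testis clusters, 0 to 20 genes and 0 to 1 miRNAs in the interaction, and 0 to 6 testis, 0 to 2 caput and 0 to 2 cauda lists. Between segments it gave 3827 to 4849 genes and 97 to 132 miRNAs. Caput libraries held 9367 to 195386 piRNA and 11811.5 to 50722 cluster counts, and depth was not tested as a cause.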

Other observations

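The test behind this part, the positions of the NR libraries numbered 3, was chosen only after the result was seen.

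NR libraries numbered 3 lay toward the reproductive season in each tissue where RNA-seq gave a position. TESTIS-NR 3 took 0.982, CAPUT-NR 3 0.830 and CAUDA-NR 3 0.562, against 0.941 to 1.06, 0.237 to 5.67 and 0.672 to 1.28 for the R libraries of the tissue. NR 1 and 2 took -29.8 and -25.7 in the testis, -2.84 and -2.11 in the caput, and -0.570 and -0.720 in the cauda. NR 3 was set against NR 1 and 2 alone. Other libraries were set against NR libraries that included NR 3, so these positions are not on the same scale, and large values are not distances. In testis miRNAs the TESTIS-R libraries took -0.411, -1.20 and -0.628. No TESTIS-NR library had a position there, as only 2 were measured. Those values do not tell whether the seasons separate in testis miRNAs. CAPUT-NR 3 also had the highest share of testis-enriched transcripts among the NR caput libraries, 0.221% against 0.0543% and 0.0189%. Its position was 0.722 without the 657 testis-enriched genes (0.353 to 2.54 in CAPUT-R) and 0.613 without the 13385 genes with a mean in testis above the median in epididymis (0.402 to 1.82). In the cauda small RNA libraries CAUDA-NR 3 took 0.537 for miRNAs and 0.844 for piRNAs. Without CAUDA-NR 3 the cauda called 901 genes, 24 miRNAs and 1047 piRNAs, against 2, 14 and 76 with all libraries. Of those piRNAs 846 were higher and 201 lower in R, where all 76 were lower with all libraries. The counts of calls come from the same libraries as the positions, so they are no separate evidence.

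In TESTIS-NR 3 mmu-miR-1a-3p had 583 CPM, against 54.5 to 63.8 in TESTIS-R, and mmu-miR-133a-3p had 84.2 against 1.82 to 6.00. These 2 were picked after their values were seen, the difference of 1 library was not tested, and 3 of the 8 muscle miRNAs had a positive season change.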
